A study of Homo sapiens with 24 samples.

How the data were processed

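Gene expression was measured on 24 Illumina HumanWG-6 v3 BeadChip arrays, which carry 48803 gene probes here. The samples were sorted fractions of 2 human induced pluripotent stem cell lines, with 3 arrays for each line and fraction. Per the file headers, the deposited scanner table was written by BeadStudio 3.2.6 without normalization and gives for every probe and array an intensity averaged over beads, the number of beads and a detection value. The deposited detection score runs from 0 to 1 and equals 1 minus the detection p-value, as a comparison of the column with the intensities showed. A second deposited table holds the authors' processed intensity values of the same arrays, and the submitters' processing notes name RMA and BeadStudio. In that table every column had the median 7.062, and each column ranked the probes as the same array of the scanner table did (rank correlation 1.0, at most 0.899 with any other array). Its values are on a linear scale up to 37764.7, with no centring of genes, and how the background was handled is not given in the sources used here. All signed values below are differences of log2 values with the direction as named.

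The scanner intensities were normalized with limma 3.58.1 in R 4.3.3 by neqc, which fits a normal-exponential background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes were kept where the detection p-value was under 0.01 in at least 3 of the 24 arrays, which left 21846 probes. For each gene symbol the kept probe with the highest mean over all 24 arrays was used, blind to group, and probes without a symbol were tested as features of their own. This gave 17005 tested features, of which 1855 had no symbol. Names in the array file were brought up to date with the reference gene tables: 15523 target names were current, 2943 were updated through a single older symbol, 297 were kept because an older symbol fitted several genes, and 6395 were kept unmatched. A further 12646 probes carried only a cluster name. Left out before any test were 139 probes for Y-linked genes and genes of X inactivation, which are not reported here. Other probes of a named gene were compared with the chosen probe, and the widest disagreements are stated at a mention of the gene. Probes of close paralogs can bind the same RNA, as for POU5F1 and POU5F1B or the MT1 metallothioneins, so their values are not independent.

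A linear model with 8 group means was fitted to all 24 arrays with lmFit and eBayes (16 residual and 6.91 prior degrees of freedom), so that all groups shared 1 estimate of the spread. Every adjusted p of a gene is from this limma fit, with Benjamini-Hochberg adjustment over the 17005 features, and a gene was called below 0.05. The 8 comparisons were high against negative in each line, in both lines averaged and as a difference between lines, the 3 steps between neighbouring fractions averaged over lines, and foreskin against IMR90 in the high fraction. 24 gene lists were tested in every comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated from the data. Members were also counted when adjusted over the list alone. The lists were core pluripotency, NODAL pathway, FGF-ERK feedback, WNT targets and antagonists, stem cell surface antigens, primitive streak, endoderm, neural ectoderm, neural crest, mesenchyme and fibroblast, trophoblast and amnion, haemato-endothelial, cardiac and skeletal muscle, surface and simple epithelium, HOX genes, cell cycle, p53 targets, immediate-early and heat shock, glycolysis, mitochondrial respiratory chain, cytosolic ribosomal proteins, imprinted genes, major histocompatibility class I, and DNA methylation and chromatin of pluripotent cells. Some genes sit in more than 1 list.

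Where a gene was undetected in all 3 arrays of a group, the change is given as at least N-fold: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes (4.98 to 5.37 log2 over arrays) and the probe's own signal. No fold is given where both groups were undetected. Replicate numbers in the labels run over all fractions of a line. The array position in the files placed each line on 2 chips of 6 arrays, and each chip held 1 line. The first chip of a line held replicate 1 of all fractions and replicate 2 of negative and low, and the second chip held the remaining arrays. Chip was therefore used as a block and each comparison was also fitted within each chip, whereas a comparison of lines at 1 fraction could use chip only as a random block. On each first chip the medium and high groups held 1 array, and on each second chip the negative and low groups did. Their spread was then taken from the other groups, so that calls within a chip are weak evidence.

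Genes to be named were set by a rule. Among called genes with a log2 change of at least 1 and groups that did not overlap (not required for the line difference), it takes the 10 largest rises and 10 largest falls for high against negative in each line, and the 5 and 5 largest otherwise. It leaves out clone, locus and open reading frame names. It adds up to 4 members of each list with the smallest adjusted p, and POU5F1, NANOG, SOX2, DNMT3B, LEFTY1, GATA6, COL1A1 and CD9 in every comparison. The text names all the largest rises and falls and examples of the list members. Results of some list members are not reported here. GATA6 was removed by the filter on dim probes. ANO1, ARRB1 and LRFN5, the genes of the low-fraction overlap and the nuclear-retained genes of the closing section were chosen after their values were seen. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

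The model was tested on simulated data with the gene means and spreads of the real arrays, each gene drawn independently and without chip effects. In them 100 genes were changed by log2 1 and 100 by log2 2. For high against negative in the foreskin line 72 of 100 and 100 of 100 were recovered with 7 of 16784 unchanged genes called. For both lines averaged 95 and 100 were recovered with 6 false calls, and for the line difference 47 and 96 with 4. A list shifted on purpose was called in each of these (adjusted p = 1.08e-07, 3.63e-16 and 0.00666) and 0 of the 23 other lists were. As the simulated genes were independent, this is no measure of false list calls where list members are correlated. Alternatives tried were quantile normalization without background correction, the authors' processed values, an offset of 50, no filter on dim probes, detection in all 24 arrays, every probe as its own feature, a replicate block, chip as a block, each chip alone, array weights, only the groups compared, each line alone, an estimated inter-gene correlation, and leaving out each array. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.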

Results

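Gene expression was profiled in 2 lines of human induced pluripotent stem (iPS) cells, which are somatic cells reprogrammed to a state like that of embryonic stem cells. One line was derived from foreskin cells and the other from IMR90, a lung fibroblast line. Cultures were sorted by flow cytometry on 2 surface antigens of human pluripotent cells, the GCTM-2 epitope and the tetraspanin CD9, into negative, low, medium and high fractions. Each of the 8 groups held 3 arrays. The series text places the collection over consecutive passages of each line, so the p-values measure the spread between samples of 1 line, part of which may be technical. The arrays had median signals of 63.9 to 83.1, and 16164 to 19243 probes (33.1% to 39.4%) were detected on each. The first principal component held 43.2% of the variance and the second 20.1%. In the negative fraction of the IMR90 line a mean of 16772 probes was detected, against 18032 in its high fraction, and in the foreskin line these means were 17580 and 17615.

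The first question was which genes part the ends of the antigen gate. In the foreskin line 24 of 28 core pluripotency genes were higher in the high fraction. CDH1, which encodes the adhesion molecule E-cadherin, was 50.4-fold higher (log2 5.66, SE 0.35, n = 3 against 3, limma adjusted p = 1.47e-11). POU5F1, the gene of the pluripotency factor OCT4, was 19.8-fold higher (log2 4.31, SE 0.27, limma adjusted p = 1.85e-11), and NANOG, which encodes another such factor, 7.83-fold. Among lower genes, POU3F2, a transcription factor of neural progenitors, was 57.9-fold lower (log2 -5.86, SE 0.40), and COL2A1, a cartilage collagen, at least 40.1-fold lower. The other largest rises were in SCNN1A, a subunit of the epithelial sodium channel (48.5-fold), KIF1A, a vesicle motor (log2 5.35), the metallothioneins MT1H (32.0-fold) and MT1G (29.0-fold), PLAAT3 (25.5-fold), COBL (25.3-fold), the tight junction gene CLDN7 (23.7-fold), MAL2 (23.0-fold) and POU5F1B (22.2-fold), a paralog of POU5F1 whose probe may read the same RNA. The other largest falls were in RHOJ (at least 31.6-fold), the secreted WNT antagonist FRZB (37.2-fold), FOXC1 (36.3-fold), TNFRSF19 (36.0-fold), LRRC4C (at least 26.0-fold), the myelin gene PMP22 (34.3-fold), ISLR (at least 20.5-fold) and SLIT2, an axon guidance cue (32.7-fold). The other probes of COL2A1 and TNFRSF19 gave log2 -1.64 and -1.70, and those of ISLR -3.60 and -1.47.

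Of 28 measured core pluripotency genes 24 rose and 0 fell, with 25 called when adjusted over the list alone. GAL rose 20.2-fold, PRDM14 by log2 4.25 and SOX2 2.27-fold. The list shifted upward (adjusted p = 5.32e-15, and 0.0109 with an estimated correlation), with medians of 1.67 and 2.09 within the first and second chips. Among 16 stem cell surface antigens 11 rose and 1 fell (12 called when adjusted over the list alone), led by CDH1, EPCAM (14.5-fold; its other probe gave log2 0.83) and CDH3 (13.9-fold). This list had adjusted p = 2.64e-06, and adjusted p = 0.0612 with an estimated correlation. CD9, which was used in the sort and serves as a check, was 7.12-fold higher. DNMT3B, a de novo DNA methyltransferase, rose 4.72-fold, while its other 4 probes ranged from log2 -0.17 to 2.54. Of 14 surface and simple epithelium genes 10 rose and 0 fell (10 adjusted over the list alone), among them the keratin gene KRT19 (2.67-fold). Their shift had adjusted p = 0.000705, and adjusted p = 0.0699 with an estimated correlation.

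Lists of differentiated lineages shifted downward in the same comparison. Of 38 mesenchyme and fibroblast genes 24 fell and 7 rose (32 called when adjusted over the list alone). IGFBP5 fell 21.3-fold and PDGFRB, a receptor of stromal cells, 6.27-fold, whereas the collagen gene COL1A1 differed by log2 0.17 (adjusted p = 0.655). The list had adjusted p = 6.21e-06, and adjusted p = 0.0612 with an estimated correlation. Among 17 neural crest genes 7 fell and 1 rose (8 adjusted over the list alone), with SOX9 31.0-fold and SNAI2 16.6-fold lower (adjusted p = 0.00162, and adjusted p = 0.0783 with an estimated correlation). Of 24 neural ectoderm genes 10 fell and 0 rose (10 adjusted over the list alone), including FABP7 (9.12-fold) and NCAM1 (5.65-fold; its other probe gave log2 -0.83). That list had adjusted p = 0.000775, and adjusted p = 0.0783 with an estimated correlation. Of 16 haemato-endothelial genes 9 fell and 1 rose (10 adjusted over the list alone), with CDH5, which encodes VE-cadherin, at least 5.11-fold lower (adjusted p = 0.000319, and adjusted p = 0.0612 with an estimated correlation). Of 18 WNT targets and antagonists 12 fell and 2 rose (14 adjusted over the list alone; adjusted p = 4.46e-06, and 0.0467 with an estimated correlation). Among 15 primitive streak genes 8 fell and 0 rose (9 adjusted over the list alone), with APLNR 15.3-fold and EOMES (log2 -2.58) lower (adjusted p = 0.000875, and adjusted p = 0.40 with an estimated correlation). Of 14 HOX genes 5 fell and 0 rose (5 adjusted over the list alone; adjusted p = 0.0186, and adjusted p = 0.505 with an estimated correlation). Of 21 endoderm genes 9 fell, such as FOXA2 (6.91-fold), and 3 rose, such as APOE (2.79-fold), with 13 called when adjusted over the list alone. The endoderm call (adjusted p = 0.0439, and adjusted p = 0.678 with an estimated correlation) was lost with chip as a block (0.0562), and without the negative arrays of replicate 1 (0.0607) or 2 (0.0532) or the high array of replicate 3 (0.0541).

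The remaining 13 lists were not called in the foreskin line. NODAL pathway genes went both ways (6 up and 4 down of 17, adjusted p = 0.601), with NODAL itself 11.8-fold and LEFTY1 4.76-fold higher. So did FGF-ERK feedback genes (6 up and 8 down of 18, adjusted p = 0.498), where FGF2 was 6.33-fold higher and DUSP6, a phosphatase induced by ERK signalling, 7.16-fold lower. The p53 targets had 9 up and 2 down of 19 (adjusted p = 0.0974) and the DNA methylation and chromatin list 7 up and 4 down of 16 (adjusted p = 0.209). For trophoblast and amnion genes (3 up and 4 down of 15, adjusted p = 0.96) the median was 0.27 while the test leaned downward. For imprinted genes (4 up and 6 down of 19, adjusted p = 0.631) the median was 0.12 and the mean -0.20. The others were cardiac and skeletal muscle (4 up, 3 down, adjusted p = 0.758), cell cycle (8 up, 4 down, 0.52), immediate-early and heat shock (3 up, 5 down, 0.852), glycolysis (5 up, 1 down, 0.203), mitochondrial respiratory chain (0 up, 0 down, 0.76), cytosolic ribosomal proteins (1 up, 1 down, 0.758) and major histocompatibility class I (4 up, 2 down, 0.167). In all, 6086 of 17005 features were called in the foreskin line, 3195 higher and 2891 lower in the high fraction, and 1339 and 1061 of these changed at least 2-fold. Groups did not overlap for 5787 of the called features. Chance gives 10% for 3 against 3 among features not chosen by a call, so this share is no test of the call. A fit with chip as a block called 6123, and within the first and second chips 2902 and 3342. Over all features the differences of the 2 chips correlated at r 0.886.

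In the IMR90 line the same comparison again placed pluripotency genes in the high fraction. NANOG was 8.86-fold higher (log2 3.15, SE 0.31, n = 3 against 3, limma adjusted p = 2.81e-08), POU5F1 8.21-fold, and PRDM14, a regulator of germ cells and pluripotency, 8.72-fold. DLK1, an imprinted gene of many progenitors, was 72.7-fold lower (log2 -6.19, SE 0.29, limma adjusted p = 3.89e-13). The eye and forebrain factor LHX2 was at least 29.4-fold lower and the WNT antagonist DKK1 40.0-fold lower. The other largest rises were in the noncoding RNA MIAT (12.1-fold; a nuclear transcript, a class weighed against RNA yield in the closing section), TRIML2 (11.5-fold), GNA14 (9.75-fold), CHST4 (9.64-fold), SCG3 (9.42-fold or log2 3.24), IDO1, an enzyme of tryptophan breakdown (9.23-fold), CD9 (8.67-fold, a check of the sort) and PILRB (8.60-fold; its other probe gave log2 0.31). The other largest falls were in LGI1 (at least 44.7-fold; its other probe gave log2 -2.76), POU3F2 (at least 31.2-fold), WLS, which carries WNT proteins to the cell surface (43.3-fold), CNTFR (38.4-fold; its other probe gave log2 -1.09), COL2A1 (36.0-fold; its other probe gave log2 -2.08), the apolipoprotein gene APOA2 (34.0-fold) and FOXC1 (32.2-fold).

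Of 28 core pluripotency genes 22 rose and 0 fell in the IMR90 line (24 adjusted over the list alone; adjusted p = 2.16e-13, and 0.00669 with an estimated correlation). DPPA4 (log2 2.77) rose and so did DNMT3B (4.58-fold), while SOX2 (log2 0.22, adjusted p = 0.505) and LEFTY1 (log2 0.59, adjusted p = 0.195) were not called. Neural ectoderm genes fell together, 21 of 24 with 0 rising (21 adjusted over the list alone), with PAX6 at least 12.4-fold lower. The neural ectoderm list had adjusted p = 1.51e-15 (0.000847 with an estimated correlation) and medians of -2.17 and -1.66 within the first and second chips. Of 21 endoderm genes 18 fell and 1 rose (20 adjusted over the list alone), with TTR, a transport protein of yolk sac and liver, 25.1-fold and SOX17 13.8-fold lower (adjusted p = 1.24e-11, and 0.041 with an estimated correlation). Among 17 neural crest genes 13 fell and 1 rose (15 adjusted over the list alone), with TFAP2B at least 11.6-fold lower (adjusted p = 1.86e-08, and 0.00669 with an estimated correlation). Of 38 mesenchyme and fibroblast genes 25 fell and 3 rose (28 adjusted over the list alone; adjusted p = 3.31e-10, and 0.0102 with an estimated correlation), with COL1A1 at log2 -0.19 (adjusted p = 0.608). Of 14 HOX genes 11 fell and 0 rose (11 adjusted over the list alone), HOXB2 at least 16.8-fold (adjusted p = 5.4e-08, and 0.0456 with an estimated correlation). WNT targets and antagonists had 10 down and 0 up of 18 (11 adjusted over the list alone; adjusted p = 6.06e-05, and 0.0426 with an estimated correlation).

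The other 6 list calls in the IMR90 line were lost with an estimated correlation. These were the surface antigens (12 up and 1 down of 16; adjusted p = 6.34e-05, and adjusted p = 0.0777 with an estimated correlation), primitive streak (6 down and 0 up of 15; adjusted p = 0.000354, and adjusted p = 0.261 with an estimated correlation) and trophoblast and amnion (6 down and 0 up of 15; adjusted p = 0.000361, and adjusted p = 0.08 with an estimated correlation). Cell cycle genes had 12 up and 1 down of 30, among them the kinetochore motor CENPE at 2.97-fold (adjusted p = 0.00339, and adjusted p = 0.261 with an estimated correlation). The DNA methylation and chromatin list had 9 up and 1 down of 16 (adjusted p = 0.0062, and adjusted p = 0.264 with an estimated correlation), and imprinted genes 8 down and 3 up of 19 (adjusted p = 0.0229, and adjusted p = 0.247 with an estimated correlation). The imprinted call was lost without the high array of replicate 1 (0.0512) and, like that of the DNA methylation list, within the second chip (0.0903 and 0.0559). Chip as a block added 1 list call. The cytosolic ribosomal list gained a call without the negative array of replicate 2 (median -0.18, adjusted p = 0.0305) or the high array of replicate 3 (median -0.24, adjusted p = 0.0222). In all, 6543 features were called in this line, 3551 higher and 2992 lower in the high fraction (1215 and 1342 at least 2-fold). Of these, 6044 had groups that did not overlap (10% by chance among features not chosen by a call). The chip block gave 6724 calls, within the first and second chips 4475 and 3242, with r 0.803 between chips over all features.

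Averaged over both lines, 25 of 28 pluripotency genes were higher in the high fraction, and 19 of 24 neural ectoderm and 28 of 38 mesenchyme and fibroblast genes were lower. CDH1 was 17.7-fold higher (log2 4.14, SE 0.25, n = 6 against 6, limma adjusted p = 3.01e-12), followed by SCNN1A (15.3-fold), TRIML2 (log2 3.81), the microtubule gene MAP7 (12.9-fold) and PRDM14 (12.9-fold). POU3F2 was at least 42.5-fold lower, COL2A1 at least 38.0-fold, LGI1 at least 26.5-fold, FOXC1 34.2-fold and the receptor gene CNTFR 31.0-fold. POU5F1 was 12.8-fold, NANOG 8.33-fold, DNMT3B 4.65-fold, LEFTY1 2.68-fold and SOX2 1.63-fold higher (adjusted p = 0.00131 for SOX2), and COL1A1 differed by log2 -0.01 (adjusted p = 0.977). The growth factor gene FGF2 and the proto-oncogene MYC were 5.79-fold and 5.63-fold higher, and the antigen-processing genes PSMB8 and TAP1 were 5.79-fold and 5.23-fold higher. The imprinted noncoding RNA H19 was 3.53-fold lower.

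Across both lines 25 of 28 pluripotency genes rose (26 adjusted over the list alone; adjusted p = 1.93e-14, and 0.00648 with an estimated correlation), and 12 of 16 surface antigens rose (13 adjusted over the list alone; adjusted p = 1.18e-06, and 0.0336 with an estimated correlation). Neural ectoderm (19 of 24 fell; adjusted p = 2.09e-10), neural crest (13 of 17; 2.04e-06), mesenchyme and fibroblast (28 of 38; 5.01e-08) and WNT genes (12 of 18; 4.27e-06) also held with an estimated correlation. The falls of primitive streak (11 of 15; adjusted p = 0.00018, and adjusted p = 0.278 with an estimated correlation), endoderm (16 of 21; 3e-06, and adjusted p = 0.139 with an estimated correlation), haemato-endothelial (10 of 16; 0.00229, and adjusted p = 0.111 with an estimated correlation) and HOX genes (11 of 14; 1.03e-05, and adjusted p = 0.111 with an estimated correlation) did not. For NODAL pathway genes (6 up, 8 down, adjusted p = 0.935) the median was -0.12 and the mean 0.03.

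Epithelium (6 of 14 rose), cell cycle (13 of 30 rose, 3 fell) and DNA methylation genes (8 of 16 rose, 4 fell) each had adjusted p = 0.0448 over both lines, and adjusted p = 0.278, 0.44 and 0.44 with an estimated correlation. With chip as a block the epithelium and DNA methylation calls were lost (0.0636 and 0.0603). Single arrays also ended these calls. The epithelium call was lost without foreskin high replicate 2 (0.0578), foreskin negative replicate 3 (0.0608), IMR90 negative replicate 1 (0.084) or IMR90 high replicate 1 (0.0544). The cell cycle call was lost without foreskin negative replicate 1 (0.0617), foreskin high replicate 2 (0.0531) or 3 (0.0536), IMR90 high replicate 1 (0.0937) or IMR90 negative replicate 2 (0.05) or 3 (0.0795). The DNA methylation call was lost without foreskin negative replicate 1 (0.0575), foreskin high replicate 1 (0.054) or IMR90 high replicate 1 (0.0749) or 2 (0.0533). The trophoblast and amnion list gained a call without foreskin high replicate 2 (0.0482) or IMR90 negative replicate 1 (0.0486). A total of 8245 features were called, 4374 higher and 3871 lower (1150 and 1099 at least 2-fold). Blocking by chip gave 8345, within the first and second chips 5667 and 5259, with r 0.909 between chips over all features.

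**Figure D1:**
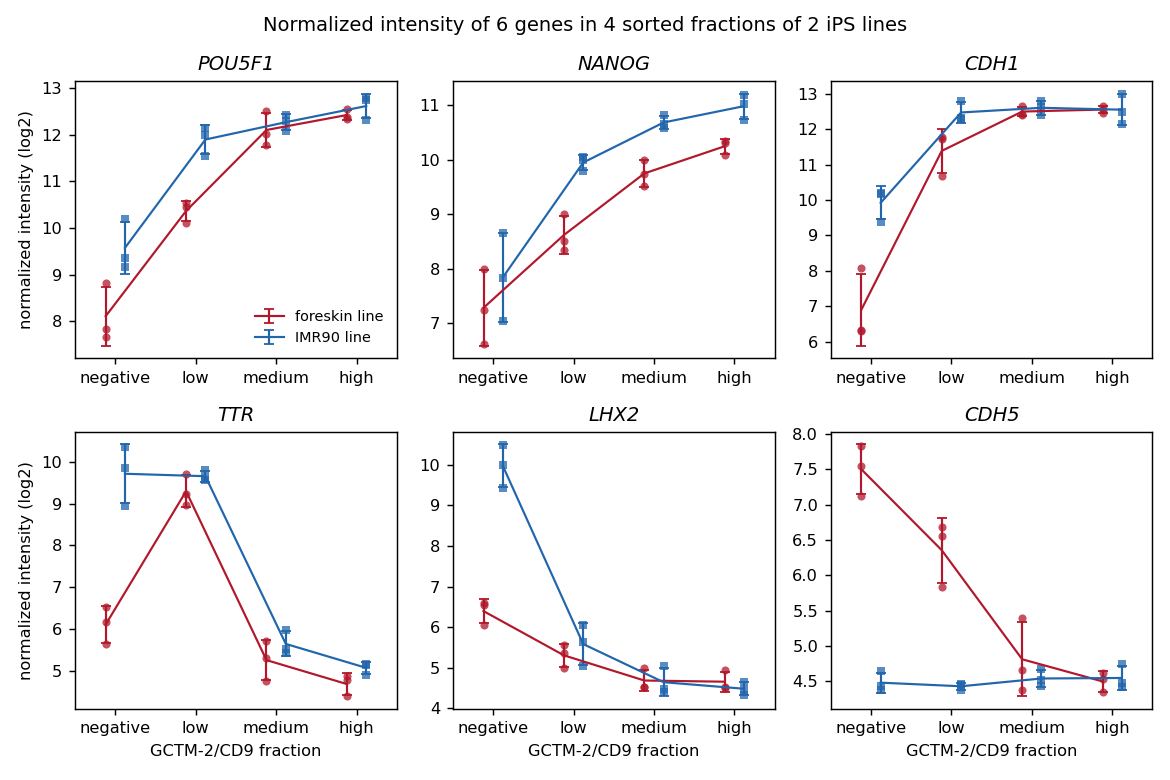
Normalized intensity (log2, y axis) of 6 genes in the negative, low, medium and high fractions (x axis) of the foreskin line (red circles) and the IMR90 line (blue squares), with a point per array and lines through the group means with bars of 1 SD (n = 3). POU5F1 rises from a mean of 8.11 to 12.42 in the foreskin line and from 9.57 to 12.61 in the IMR90 line, whereas LHX2 falls from 9.98 to 4.48 in the IMR90 line and starts at 6.39 in the foreskin line.

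The differences between high and negative fractions of the lines correlated across genes (Pearson r 0.704, Spearman rho 0.654), a description since genes are not independent replicates. The lines shared 2129 features called higher and 1686 called lower, where independent lists would share 667 and 509, and 110 were called in opposite directions. These comparisons have no array in common, but they share 1 estimate of the spread per gene, which by itself can raise the number shared. Of the called features in each line, 59.7% in the foreskin line and 51.0% in the IMR90 line had both intermediate fractions between negative and high. The jackknife SE of these shares, from leaving out each array, was 9.7 and 12.9 percentage points, so that the lines cannot be ranked by them. All fractions were in order for 51.3% and 41.5%. The low fraction had reached a median of 64.3% of the change in the foreskin line and 80.0% in the IMR90 line, and the medium fraction 91.1% and 95.2%. Taken singly, low lay between the ends for 83.3% and 74.1% of called features, and medium for 67.2% and 61.0%. As medium lay close to high, a small spread can place its mean past that of high.

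The design also asks whether the lines part at the same genes, which the difference between their high against negative changes tests directly. In the negative fraction 18 of 21 endoderm and 14 of 24 neural ectoderm genes were higher in IMR90 than in foreskin (0 and 1 lower; adjusted p = 0.0391 and 0.0152 with an estimated correlation), while neural crest genes went both ways (6 and 4 of 17, adjusted p = 0.211). DLX5, a homeobox gene of crest and skeleton, differed by log2 4.75 (SE 0.75, n = 3 in each of 4 groups, limma adjusted p = 0.000137) and LMO3 by 4.30. PAX6, the eye and forebrain factor, differed by 4.23, TFAP2B by 4.09 and DLK1 by 3.90, and PAX6 and TFAP2B were undetected in the high and negative arrays of the foreskin line, so that their values are set partly by the background. DLX5 and MPPED2 were also undetected in at least 1 of the 4 groups. The other way, PPP1R17 differed by -4.29, MPPED2 by -4.16, TM4SF18 by -4.10, the prohormone convertase gene PCSK1 by -3.94 and GNA14 by -3.81. Endothelial genes went both ways. CDH5 (-3.07; of these 4 groups detected only in foreskin negative, so that its value too is set partly by the background), SOX18 (-2.20) and the TGF-beta co-receptor gene ENG (-1.66) were more negative in the foreskin line. VWF, the gene of von Willebrand factor (1.83), and EGFL7 (1.22) were more negative in the IMR90 line. SOX18, ENG, VWF, EGFL7 and PCSK1 were not called in the second chips alone. The EGFL7 call was lost without foreskin negative replicate 1 or 2, foreskin high replicate 1, 2 or 3, IMR90 negative replicate 1 or 3 or IMR90 high replicate 1 or 2 (adjusted p = 0.0583 to 0.129). CDH1 (3.02), EPCAM (2.40; its other probe gave -0.32), NODAL (2.59) and KRT19 (2.58) also differed, with more of their RNA in the IMR90 negative fraction than in the foreskin one. CDH1 stood at a mean log2 intensity of 9.92 there and 6.90 in the foreskin negative fraction. Where the lines were compared within the negative fraction, for lists or genes, line and chip cannot be separated, as each chip held 1 line.

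Endoderm genes differed most widely, with 15 of 21 called, all positive (17 adjusted over the list alone; median 1.58, adjusted p = 2.81e-13, and 0.0494 with an estimated correlation). Their medians were 1.36 and 2.12 within the first and second chips. Neural ectoderm genes had 11 of 24 called, all positive (12 adjusted over the list alone; adjusted p = 1.27e-08, and 0.0189 with an estimated correlation), with medians of 1.0 and 0.61 within chips. Trophoblast and amnion genes had 6 of 15 (9 adjusted over the list alone; adjusted p = 4.22e-06, and 0.0494 with an estimated correlation), among them ISL1 (3.03). The next calls were lost with an estimated correlation. They were neural crest (6 up, 2 down; adjusted p = 0.00228, and adjusted p = 0.122 with an estimated correlation), HOX genes (6 up; 8.98e-06, and adjusted p = 0.126 with an estimated correlation), epithelium (5 up; 0.00051, and adjusted p = 0.0875 with an estimated correlation), surface antigens (8 up, 3 down; 0.0142, and adjusted p = 0.263 with an estimated correlation), cardiac and skeletal muscle (2 up, 1 down; 0.013, and adjusted p = 0.263 with an estimated correlation), imprinted genes (2 up; 0.0109, and adjusted p = 0.184 with an estimated correlation), cytosolic ribosomal proteins (0 called; 0.0151, and adjusted p = 0.307 with an estimated correlation), cell cycle (1 down; 0.00561, and adjusted p = 0.263 with an estimated correlation) and haemato-endothelial genes (2 up, 4 down; 0.0151, and adjusted p = 0.209 with an estimated correlation).

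The haemato-endothelial median was -0.61 in the first chips and -0.05 in the second, where it was not called (0.675), and the call was lost without IMR90 negative replicate 2 (0.0754). The surface antigen call was lost in the first chips (0.304) and without IMR90 negative replicate 2 (0.055), the epithelium call in the first chips (0.0912), the cardiac call without IMR90 high replicate 1 (0.0575), the ribosomal call in the second chips (0.175) and without IMR90 high replicate 1 (0.0725) or IMR90 negative replicate 3 (0.0545), and the imprinted call in the second chips (0.133). NODAL pathway genes (4 up of 17, adjusted p = 0.0663) gained a call with chip as a block (0.0252) and without foreskin high replicate 3 (0.0219), IMR90 negative replicate 1 (0.0388) or IMR90 high replicate 2 (0.0402). The mesenchyme list gained one without foreskin high replicate 1 (0.0346) or foreskin negative replicate 2 (0.0306). So did the p53 list without foreskin negative replicate 3 (0.0375) or IMR90 high replicate 2 (0.0402), and the DNA methylation list without IMR90 high replicate 3 (0.0419). Pluripotency genes were not called (5 up and 2 down of 28, adjusted p = 0.191) except without IMR90 negative replicate 1 (0.0338), with NANOG at log2 -0.18 (adjusted p = 0.854) and SOX2 at 0.96 (adjusted p = 0.075). POU5F1 (1.27, adjusted p = 0.0381) and LEFTY1 (1.66, adjusted p = 0.0342) were called. With chip as a block POU5F1 was not called (0.063) and SOX2 was (0.008). The POU5F1 call was lost without foreskin high replicate 1, 2 or 3, foreskin negative replicate 2 or 3, IMR90 negative replicate 2 or IMR90 high replicate 2 (adjusted p = 0.0523 to 0.116). The LEFTY1 call was lost without foreskin high replicate 1 or 2, foreskin negative replicate 2 or 3, IMR90 negative replicate 1 or 3 or IMR90 high replicate 1 (adjusted p = 0.0532 to 0.104). In all, 1645 features were called, 954 positive and 691 negative, of which 754 and 460 by at least 2-fold. Blocking by chip gave 1962 calls, within the first and second chips 454 and 699, with r 0.557 between chips over all features. Detection in all 24 arrays left 1084.

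**Figure D2:**
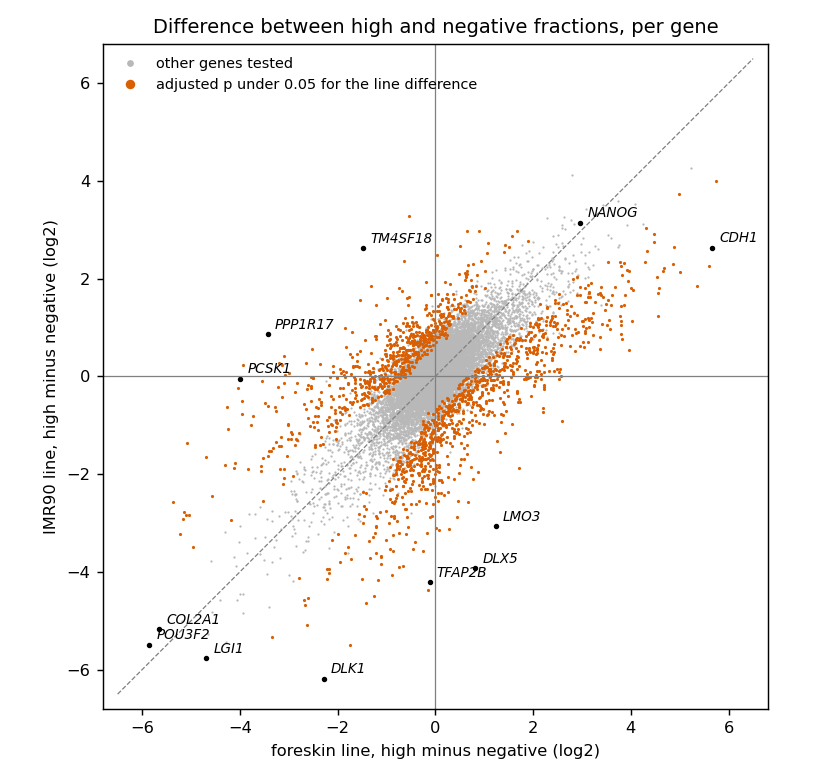
Difference between high and negative fractions (log2) for each tested gene in the foreskin line (x axis) and the IMR90 line (y axis), with genes called for the line difference in orange, others in grey, 12 named genes in black and a dashed line of equal change. The cloud follows the dashed line (Pearson r 0.704 across genes), and the 1645 orange points lie off it on both sides.

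The steps between neighbouring fractions asked where along the gate expression changes. Between negative and low, with lines averaged, 22 of 28 pluripotency genes already rose. CDH1 was 11.5-fold higher in low (log2 3.52, SE 0.25, n = 6 against 6, limma adjusted p = 1.99e-10), SCNN1A 10.2-fold (log2 3.36) and MAP7 8.10-fold. MIAT (12.5-fold) and GOLGA8B (8.94-fold), whose transcripts stay in the nucleus or keep introns, were higher too, and their class is weighed against RNA yield in the closing section. SCRG1 was at least 16.2-fold lower, POU3F2 20.6-fold, the nuclear receptor gene NR2F1 at least 10.9-fold, COL2A1 log2 -3.63 and CNTFR 9.75-fold (log2 -3.29). POU5F1 rose 4.88-fold, NANOG 3.30-fold and DNMT3B 3.16-fold, while SOX2 was not called (log2 0.42, adjusted p = 0.0506). SOX2 was called without foreskin negative replicate 2 (0.0273) or foreskin low replicate 3 (0.000215).

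Pluripotency genes (22 of 28 rose, 23 adjusted over the list alone), surface antigens (13 of 16 rose, 13 adjusted over the list alone), neural ectoderm (17 of 24 fell, 1 rose), neural crest (11 of 17 fell) and mesenchyme and fibroblast genes (25 of 38 fell, 4 rose) shifted between negative and low (adjusted p = 1.1e-11, 6.17e-08, 1.44e-09, 8.2e-06 and 1.63e-07). These held with an estimated correlation, and 6 further calls did not. Endoderm genes, unlike the neural, crest and mesenchyme lists, had 14 of 21 higher in low and 0 lower (17 adjusted over the list alone; median 0.67, adjusted p = 2.92e-05, and adjusted p = 0.207 with an estimated correlation), and medians of 0.73 and 0.55 within chips. AFP, the fetal serum protein of yolk sac and liver, rose 4.07-fold. TTR rose 2.96-fold on average, from 3.19 (log2) in the foreskin line and -0.06 in the IMR90 line (adjusted p = 0.909), and LEFTY1 (0.99 on average, log2) was at -0.17 in the IMR90 line and not called there. In the foreskin line alone 19 of 21 endoderm genes rose (median 1.71, adjusted p = 0.0207 with an estimated correlation), in the IMR90 line 2 rose and 3 fell (median -0.24), and the difference between lines was called for 16 of 21 (median 2.16, adjusted p = 0.0045 with an estimated correlation). HOX genes (11 of 14 fell; adjusted p = 4.7e-07, and adjusted p = 0.0755 with an estimated correlation), WNT genes (11 of 18 fell; 0.000739, and adjusted p = 0.0864 with an estimated correlation), epithelium (10 of 14 rose; 0.00296, and adjusted p = 0.105 with an estimated correlation), the DNA methylation list (9 of 16 rose; 0.0182, and adjusted p = 0.40 with an estimated correlation) and primitive streak (5 of 15 fell; 0.0219, and adjusted p = 0.597 with an estimated correlation) were also called. The primitive streak call was lost without foreskin negative replicate 1 (0.0665), IMR90 low replicate 2 (0.0506) or IMR90 negative replicate 3 (0.0999). Haemato-endothelial genes (4 of 16 fell, adjusted p = 0.0573) were called without foreskin negative replicate 3 (0.0292), foreskin low replicate 3 (0.0431), IMR90 negative replicate 1 (0.042) or 2 (0.027) or IMR90 low replicate 1 (0.0356). In all, 6699 features were called between negative and low, 3582 higher and 3117 lower in low, with 7045 when chip was a block, 5312 and 2658 within the first and second chips, and r 0.855 between chips over all features. The foreskin line alone had 3941.

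Between low and medium the largest changes were falls of endoderm genes. TTR was 16.3-fold lower in medium (log2 -4.03, SE 0.21, n = 6 against 6, limma adjusted p = 9.33e-12), and APOA2 15.5-fold, APOA1 14.5-fold, the WNT antagonist DKK4 11.1-fold (log2 -3.47) and the fibrinogen gene FGB 8.12-fold lower (its other probe gave log2 -0.88). SOX17 and FOXA2, transcription factors of early endoderm, were 8.08-fold and 7.74-fold lower, and EOMES and LHX1, genes of the primitive streak, 4.19-fold and 3.64-fold. The largest rises were smaller, in NPTX1 (2.44-fold or log2 1.29), DACT1 (2.23-fold), KIF1A (2.21-fold), MYC (2.18-fold) and the NOTCH target HEY2 (2.15-fold). POU5F1 rose 2.07-fold (log2 1.05, adjusted p = 0.000934), NANOG 1.91-fold and CD9 by log2 0.59, while DNMT3B, SOX2, LEFTY1 and COL1A1 were not called. In the IMR90 line alone the medium minus low difference of POU5F1 was 0.37 (log2) and not called.

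Of 21 endoderm genes 19 fell between low and medium and 0 rose (20 adjusted over the list alone; median -1.64, adjusted p = 5.98e-48, and 0.000267 with an estimated correlation), with medians of -1.66 and -1.54 within chips. Within the lines 17 fell in foreskin and 13 in IMR90. Pluripotency (9 of 28 rose, 16 adjusted over the list alone), WNT (6 of 18 fell), neural ectoderm (8 of 24 fell), neural crest (5 of 17 fell, 1 rose), mesenchyme and fibroblast (12 of 38 fell, 1 rose), trophoblast and amnion (5 of 15 fell) and haemato-endothelial genes (4 of 16 fell) were called too (adjusted p = 1.01e-12, 1.26e-07, 1.12e-06, 0.000178, 2.56e-10, 1.35e-07 and 0.000122), and all 7 held with an estimated correlation. Calls lost that way were primitive streak (4 of 15 fell; adjusted p = 8.8e-06, and adjusted p = 0.161 with an estimated correlation), cardiac and skeletal muscle (4 of 13 fell; 3.98e-05, and adjusted p = 0.0517 with an estimated correlation), imprinted genes (4 of 19 fell; 0.0156, and adjusted p = 0.178 with an estimated correlation), the DNA methylation list (4 of 16 rose; 0.0195, and adjusted p = 0.394 with an estimated correlation) and cell cycle (0 called; 0.0378, and adjusted p = 0.471 with an estimated correlation). The cell cycle call and those of imprinted and DNA methylation genes were not kept in the first chips (0.657, 0.0781 and 0.657). The DNA methylation call was lost without foreskin medium replicate 2 (0.126) or IMR90 low replicate 2 (0.0565), and the cell cycle call without foreskin low replicate 1 (0.116), foreskin medium replicate 2 (0.17), IMR90 low replicate 2 (0.103) or IMR90 medium replicate 3 (0.0561). The major histocompatibility class I list gained a call without foreskin low replicate 3 (0.0445). In all, 1024 features were called, 453 higher and 571 lower in medium (28 and 188 at least 2-fold), with 1150 when chip was a block, 110 and 483 within the first and second chips, and r 0.592 between chips over all features. Detection in all 24 arrays left 626, and the IMR90 line alone had 234.

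**Figure D3:**
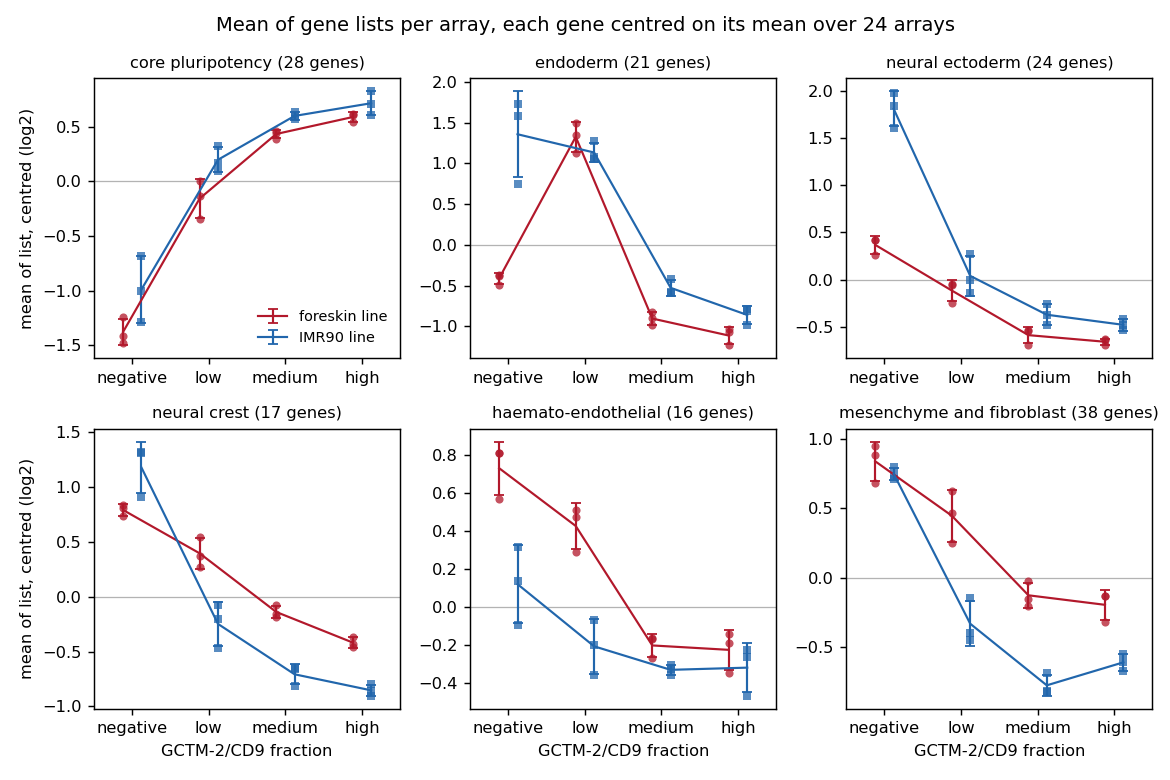
Mean of 6 gene lists per array (y axis, log2, each gene centred on its mean over the 24 arrays) in the negative, low, medium and high fractions (x axis) of the foreskin line (red circles) and the IMR90 line (blue squares), with a point per array and lines through the group means with bars of 1 SD (n = 3). Endoderm genes peak in the low fraction of the foreskin line (19 of 21 higher than in negative, 17 lower in medium than in low, and 16 both), while in the IMR90 line they lie as high in negative as in low.

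The medium and high fractions differed in few genes. ABHD12B was 2.69-fold higher in high (log2 1.43, SE 0.13, n = 6 against 6, limma adjusted p = 2.99e-06), and FOXA2, the early endoderm factor, was 2.07-fold lower (log2 -1.05, SE 0.16, adjusted p = 0.00964). Of the 6 features called, 4 were higher and 2 lower, and 833 had an unadjusted p under 0.05. ANO1, a chloride channel gene (-0.78, adjusted p = 0.0107), the arrestin gene ARRB1 (0.57, adjusted p = 0.0197), LRFN5 (0.93, adjusted p = 0.03) and 1 probe without a symbol completed them, and these were chosen after their values were seen. Without foreskin medium replicate 2 only 1 feature was called, and ANO1 (0.0642), ARRB1 (0.106), LRFN5 (0.138) and FOXA2 (0.055) were not. ARRB1 and LRFN5 were also lost without foreskin high replicate 2 (0.0554 and 0.0962) or 3 (0.0929 and 0.0929), IMR90 high replicate 2 (0.103 and 0.108) or 3 (0.0555 and 0.125) or IMR90 medium replicate 3 (0.13 and 0.185), and LRFN5 without foreskin medium replicate 1 (0.143), foreskin high replicate 1 (0.0659) or IMR90 medium replicate 2 (0.0988). POU5F1 (log2 0.33), NANOG (0.40), DNMT3B (0.08), SOX2 (0.03), LEFTY1 (0.40), CD9 (0.10) and COL1A1 (0.32) each had adjusted p = 0.998.

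Pluripotency genes as a list leaned upward from medium to high (0 of 28 called, 1 adjusted over the list alone; median 0.09, adjusted p = 0.00738, and adjusted p = 0.515 with an estimated correlation) and endoderm genes downward (1 of 21 called, 5 adjusted over the list alone; median -0.13, adjusted p = 0.0002, and adjusted p = 0.515 with an estimated correlation). Neural crest (median -0.06, adjusted p = 0.0286) and trophoblast and amnion genes (median -0.21, adjusted p = 0.00745) leaned downward with 0 members called, each with adjusted p = 0.515 with an estimated correlation. The pluripotency, neural crest and trophoblast calls were lost in the second chips (0.145, 0.074 and 0.074), and the neural crest one in the first chips (0.09). The pluripotency call was lost without IMR90 high replicate 1 (0.11), and the trophoblast call without foreskin medium replicate 2 (0.156) or foreskin high replicate 3 (0.0504). The neural crest call was lost without foreskin high replicate 1 (0.0761) or 3 (0.0529), foreskin medium replicate 2 (0.0517), IMR90 medium replicate 1 (0.0548) or 3 (0.0689), or IMR90 high replicate 1 (0.0799) or 2 (0.0716). Other lists gained calls. Without foreskin medium replicate 3 these were p53 (0.0304), class I (0.0422) and DNA methylation (0.0304). DNA methylation was also called without IMR90 medium replicate 1 (0.0301) or IMR90 high replicate 1 (0.022). The mitochondrial list was called without IMR90 high replicate 1 (0.022), p53 without IMR90 high replicate 3 (0.039) and WNT without IMR90 medium replicate 2 (0.0499). A block for chip gave 8 calls, and within the first and second chips 0 and 1, with r -0.12 between chips over all features. Array weights gave 34 calls, and detection in all 24 arrays or only the groups compared gave 3. Each first chip held 1 medium and 1 high array.

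The last comparison set the lines side by side in the high fraction, where 3 of 28 core pluripotency genes were higher in the foreskin line and 1 lower (5 adjusted over the list alone; adjusted p = 0.407). GAL was 2.45-fold, GDF3 1.96-fold and DPPA2 1.92-fold higher, and CUZD1 3.52-fold lower. The GAL call was lost without IMR90 high replicate 1 (0.0642), the GDF3 call without foreskin high replicate 2 (0.0838) or 3 (0.106) or IMR90 high replicate 1 (0.106) or 2 (0.0869), and the DPPA2 call without foreskin high replicate 3 (0.115) or IMR90 high replicate 1 (0.0577) or 2 (0.0702). POU5F1 (log2 -0.19, adjusted p = 0.806), SOX2 (-0.22), DNMT3B (-0.52), NANOG (-0.74, adjusted p = 0.215), LEFTY1 (-1.15, adjusted p = 0.0644) and CD9 (0.13) were not called, which does not show that they were equal. EDNRB, the endothelin B receptor gene, was 57.7-fold higher in the foreskin line (log2 5.85, SE 0.33, n = 3 against 3, limma adjusted p = 1.44e-11), though its other probes gave log2 0.02 and 4.22. GSTT1 (at least 19.6-fold), NLRP2 (at least 17.7-fold), TRIM4 (at least 8.28-fold) and ZNF558 (12.5-fold) were also higher there. LDOC1 (at least 29.9-fold), the imprinted gene NNAT (at least 22.6-fold; its other probe gave log2 -2.72), LLPH (at least 6.37-fold), IAH1 (8.13-fold) and SLITRK4 (7.39-fold, log2 -2.89) were lower in the foreskin line. LEFTY1 was called without foreskin high replicate 2 (0.0175).

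Of 19 p53 targets 7 were higher in the foreskin line and 0 lower (13 adjusted over the list alone; median 0.48, adjusted p = 4.06e-10, and 0.0299 with an estimated correlation), with medians of 0.71 between the first chips of the lines (1 array against 1) and 0.59 between the second (2 against 2). CDKN1A, the cell cycle inhibitor p21, was 4.16-fold higher (log2 2.06; its other probe gave 0.14), BTG2 2.64-fold, PHLDA3 2.02-fold and RRM2B 2.01-fold. The RRM2B call was lost without foreskin high replicate 3 (0.146) or IMR90 high replicate 2 (0.11) or 3 (0.0727). Mesenchyme and fibroblast genes had 8 higher and 1 lower of 38 (15 adjusted over the list alone; adjusted p = 1.04e-05, and adjusted p = 0.147 with an estimated correlation), among them LGALS1 (5.14-fold) and ANXA1 (3.30-fold). Of 13 major histocompatibility class I genes 2 were higher (2 adjusted over the list alone; adjusted p = 0.00318, and adjusted p = 0.56 with an estimated correlation), and this call was lost in the first chips (0.0905), where it rests on 1 array against 1. The 2 class I genes called were HLA-C (2.44-fold) and TAP2 (1.68-fold), and the other probe of TAP2 went the opposite way (log2 -1.15). Neural crest genes (4 up and 1 down of 17, adjusted p = 0.131) gained a call with chip as a random block (0.00761). Without IMR90 high replicate 3 the mitochondrial list (median 0.20, adjusted p = 0.0111) and the DNA methylation list (median -0.35, adjusted p = 0.00169) gained one. Without IMR90 high replicate 1 the glycolysis list did (median 0.21, adjusted p = 0.0125). The WNT antagonist gene SFRP1 was 3.31-fold lower in the foreskin line, OTX1 at least 4.22-fold, and LEFTY2 2.45-fold, a call lost without foreskin high replicate 1 (0.0803) or IMR90 high replicate 2 (0.0812) or 3 (0.0957). In all, 772 features were called, 340 higher and 432 lower in the foreskin line, of which 767 had groups that did not overlap (10% by chance among features not chosen by a call). Without foreskin high replicate 3 the count was 484. With chip as a random block 660 were called. The first chips alone, 1 array against 1 with the spread taken from other groups, gave 59, the second chips gave 498, and r between these was 0.357 over all features. Array weights gave 2999 calls and detection in all 24 arrays 503. Each chip held 1 line, so that the chip and the line cannot be separated further in this comparison.

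Over the 8 comparisons 80 of 192 list tests were called at the preset correlation and 32 held with an estimated correlation.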

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

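The tests of the endoderm peak, of the share of undifferentiated cells and of the haemato-endothelial part were chosen only after the result was seen.

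The results of this part stood out because the change from negative to high differed between the lines, with 1645 features called. Medians over list members of the line difference per gene (log2, foreskin minus IMR90) were 1.58 for endoderm, 1.36 for trophoblast and amnion, 1.27 for HOX genes, 0.84 for neural crest, 0.77 for neural ectoderm, 0.67 for epithelium, 0.56 for surface antigens, 0.55 for cardiac and skeletal muscle, 0.29 for imprinted genes, 0.18 for cytosolic ribosomal proteins, -0.35 for cell cycle and -0.53 for haemato-endothelial genes. Genes with a more positive change in the foreskin line were DLX5 (4.75), LMO3 (4.30), PAX6 (4.23), TFAP2B (4.09), DLK1 (3.90), LHX2 (3.76), ISL1 (3.03), KIF1A (3.49), SCNN1A (3.34), TTR (3.22), CDH1 (3.02), MT1H (2.87), CLDN7 (2.77), FOXA1 (2.65), NODAL (2.59), KRT19 (2.58), HOXC6 (2.57), MT1G (2.56), COBL (2.498), MAL2 (2.49), PLAAT3 (2.47), APOA2 (2.46), SIX3 (2.44), EPCAM (2.40), DKK1 (1.99), APOE (1.88), VWF (1.83), SOX17 (1.83), GAL (1.76), POU5F1B (1.72), LEFTY1 (1.66), MAP7 (1.55), CDH3 (1.55), FOXA2 (1.33), POU5F1 (1.27), MYC (1.26) and EGFL7 (1.22). Genes with a more negative change there were PPP1R17 (-4.29), MPPED2 (-4.16), TM4SF18 (-4.10), PCSK1 (-3.94), GNA14 (-3.81), ISLR (-3.70), CDH5 (-3.07), RHOJ (-2.81), LRRC4C (-2.38), PMP22 (-2.27), TNFRSF19 (-2.25), SOX18 (-2.20), SLIT2 (-2.19), FRZB (-1.99), ENG (-1.66), SOX9 (-1.47) and DPPA4 (-0.86). DLX5, PAX6, TFAP2B, LHX2, TTR, FOXA1, SIX3, MPPED2, CDH5, ISLR, RHOJ and LRRC4C were among those undetected in 1 or more of the 4 groups, so that background sets part of their values.

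The negative fractions of the lines may hold different differentiated cells, with more neural and endodermal ones in IMR90. A smaller or larger share of undifferentiated cells in one of them would move all genes of the negative fraction the same way, but of 687 genes lower in high and called in the line difference 385 went one way and 302 (44.0%) the other, which excludes it as the only cause. For the neural ectoderm part the median was 0.61 or more within both chips. A constant offset of a chip cancels in high minus negative there and was so excluded. As each chip held 1 line, a chip effect that differs between fractions cannot be told apart from a line difference. These medians also rest on 1 high array per line in the first chips and 1 negative array per line in the second. An odd composition of 1 array was excluded, since leaving out any of the 12 left a median of 0.66 or more. For the haemato-endothelial part (-0.61 in the first chips and -0.052 in the second, adjusted p = 0.0421 with chip as a block) a chip difference cannot be told apart from biology, and its members VWF and EGFL7 went the other way.

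The endoderm peak in the low fraction of the foreskin line could come from early endoderm cells that carry some GCTM-2 and CD9. A mixture of negative and medium cells cannot exceed both of its parts, and 16 of 21 endoderm genes were called higher in low than in negative and lower again in medium, so that such a mixture was excluded. Low exceeded the higher of negative and medium by a median of 1.46 (log2), by 1.49 and 1.64 within the first and second chips, which excluded a chip difference. Leaving out any of the 9 arrays left this median at 1.39 or more, which excluded a single odd array.

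Transcripts that stay in the nucleus or keep introns, such as MIAT and GOLGA8B, were lower in the negative fractions, which may be a lower yield of nuclear RNA from these cells. In a list of 23 other measured transcripts of this kind the median of high minus negative was 0.69 (log2) in the foreskin line and 0.74 in the IMR90 line, with 12 and 16 genes called higher and 0 lower. This fits a lower nuclear yield, and a biological difference in splicing would look the same, so that the cause stays open. Whether the probes read nuclear or exported forms of these genes was not tested. A lower signal of the negative arrays was weighed by the number of probes detected. With group means removed the list mean did not follow it (Pearson r -0.051, permutation p = 0.88, and Spearman rho -0.037, permutation p = 0.892). The r was 0.047 without the 2 farthest arrays, 0.28 in the first chips and -0.44 in the second. This cannot decide the question, as removing group means removes the difference between fractions. In the foreskin line the means of probes detected were similar (17580 in negative, 17615 in high). Fewer detected probes thus do not account for the shift of 0.69 there. In the IMR90 line (16772 in negative, 18032 in high) this stays open.

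Splits of the arrays into other groups tested chance. For both lines averaged 1 of 100 splits, the real one, reached 8245 calls (highest other 4196). The same held for the line difference with 1645 (356), low against negative with 6699 (3613) and medium against low with 1024 (347). It also held for high against medium with 6 (1). Other splits can keep part of the real grouping, so they show only that none drawn gave as many calls. For high against medium chance was not excluded, as leaving out foreskin medium replicate 2 left 1 call and r between chips was -0.12. The 10 possible splits were too few for the foreskin line (6086, highest other 1), the IMR90 line (6543, highest other 1) and the lines at high (772, highest other 0), where only the real one, 1 split, reached its count.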

How the results depend on the processing

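The alternatives were chosen before the data were examined, apart from tests of gene lists by chip and by leaving out arrays, and of lists, agreement and order under quantile normalization without background correction, which were chosen only after the result was seen.

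With the authors' processed values, an offset of 50, no filter, every probe as its own feature or quantile normalization without background correction (6243, 6585, 8301, 1754, 6780, 1098, 8 and 811 calls in the order of the report) all counts stayed within 1.5 times. Agreement between lines was 0.680 to 0.721 and low and medium lay between the ends for 59.7% to 61.6% (foreskin) and 51.0% to 51.9% (IMR90). Of 222 named gene values 215 kept direction and call with the authors' processed values, 217 without a filter and 219 with quantile normalization without background correction, and of 192 list values 190 kept them with the authors' values and 185 with that quantile normalization. POU5F1 in the line difference in high vs negative was lost with the authors' processed values (0.0563) and with no filter (0.087), and SOX2 in low vs negative was gained with an offset of 50 (0.0396). The endoderm list in high vs negative of the foreskin line was lost with quantile normalization without background correction (0.11), as was the epithelium list of both lines (0.0503), and the cell cycle list, high vs negative, both lines, and the DNA methylation and chromatin of pluripotent cells list, high vs negative, both lines, were lost with the authors' processed values (0.0522 and 0.0552).

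Genes detected in all 24 arrays, fewer genes, gave 1084 calls for the line difference, 626 for medium against low, 3 for high against medium and 503 for the lines at high. Array weights gave 34 for high against medium and 2999 for the lines at high; the cause was not tested. Fitting only the groups compared, fewer arrays, gave 3 for high against medium. The foreskin line alone gave 3941 for low against negative and 2 for high against medium, and the IMR90 line alone 234 for medium against low and 1 for high against medium, again from fewer arrays. TTR (-0.058) and LEFTY1 (-0.17) reversed for low against negative in the IMR90 line alone, where both were flat; the cause was not tested. With an estimated correlation 32 of 192 list shifts were called in place of 80.

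Within the first chips, with fewer arrays, 2902 were called for foreskin high against negative, 454 for the line difference, 110 for medium against low, 0 for high against medium and 59 for the lines at high, and the mitochondrial list reversed for high against medium (-0.18 against 0.04; the cause was not tested). Within the second chips the counts were 3342 (foreskin), 3242 (IMR90), 5259 (both), 699 (line difference), 2658 (low against negative), 483 (medium against low), 1 (high against medium) and 498 (the lines at high).

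With a block for the replicate number the counts were 6687, 7042, 8730, 2175, 7187, 1283, 10 and 794, so that high against medium moved from 6 to 10; the cause was not tested. This block ended the calls of the endoderm list in the foreskin line (0.0553) and of the epithelium and DNA methylation lists in both lines (0.0623 each). It added the NODAL pathway, mesenchyme and p53 lists in the line difference (0.0407 each), the haemato-endothelial list in low against negative (0.0464) and the neural crest list at high (0.00622), and 4 named gene values. Of 18 pairs with the same number 14 in the foreskin line had a residual correlation above 0.1 (lowest -0.016) and 11 in the IMR90 line (lowest -0.043). In these lines 12 of 12 and 10 of 12 arrays were closest to their own number, a hint from the data that the numbers mark passages. Number and chip are tied in part. In the foreskin line the median r was 0.26 for the same number on the same chip. It was 0.022 for the same number on different chips and 0.027 for different numbers on the same chip. In the IMR90 line these medians were 0.11, 0.083 and -0.0038.

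Leaving out 1 array gave 5116 to 5625 calls (foreskin), 5540 to 6205 (IMR90), 7769 to 8072 (both), 1270 to 1642 (line difference), 6183 to 6660 (low against negative), 757 to 1038 (medium against low), 1 to 8 (high against medium) and 484 to 667 (the lines at high). Genes near background have compressed differences, so that folds from undetected groups are lower bounds.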

Other observations

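The test of the nuclear-retained list was written before that list was read out; the other genes and tests of this part were chosen only after the result was seen.

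Beyond the endoderm list, the low fraction of the foreskin line held a set of genes that were lower on both sides of it. SLCO2A1, a prostaglandin transporter gene, was 2.90 (log2) higher in low than in negative and 2.89 lower in medium than in low, where IMR90 differed by -0.46 between negative and low. GPX2, a glutathione peroxidase of gut epithelium, differed by 2.49 and -3.13 and was called higher in low in IMR90 as well (0.68, adjusted p = 0.0229), and PITX1, a homeobox gene of hindlimb and oral tissue, by 2.28 and -2.64. FOXQ1 (2.32 and -2.36) and KYNU, an enzyme of tryptophan breakdown (2.19 and -3.16), did likewise. In IMR90 low against negative was -0.53 for PITX1, -0.415 for FOXQ1 and -1.58 for KYNU. The foreskin medium means of PITX1 (4.89) and KYNU (4.91) lay below the lowest signal of detected probes on any array (4.98), so that background limits these falls.

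The set also held heart muscle genes. NPPB, which encodes a natriuretic peptide, differed by 2.85 and -2.15 and the atrial myosin light chain gene MYL7 by 2.28 and -2.03. ISL1, a factor of heart and pancreas progenitors (2.03 and -1.82), was in it as well. In IMR90 low against negative was 0.31 for NPPB, -0.54 for MYL7 and -1.49 for ISL1. In the foreskin line 132 features rose from negative to low and fell from low to medium, where independent lists of 2235 and 506 would share 66.5. Simulated data without any change gave 0, as they hold almost no calls, and are no measure for this number. In IMR90 the number was 8, with 26.5 from 2884 and 156. Of the measured list members 16 of 21 endoderm, 4 of 13 cardiac and skeletal muscle and 3 of 15 trophoblast and amnion genes were in the foreskin set, and 0 pluripotency, neural ectoderm or mesenchyme genes. Both calls use the same low arrays, which by itself can raise the number shared.

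Among genes of the nuclear-retained list, PNISR, a splicing-related gene, was higher in high than in negative by 1.94 (log2, foreskin) and 2.05 (IMR90). NKTR (1.57 and 1.63), ARGLU1 (1.25 and 1.35), PRP4K (1.15 and 1.65) and CCNL1 (1.03 and 1.32) were too. Members called in neither line included SREK1 (-0.18 and 0.06), SFPQ (-0.15 and 0.06), RBM39 (0.30 and -0.37) and PABPN1 (0.32 and 0.03), so that the list did not move as a whole.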
